A study of Mus musculus with 26 samples.

How the data were processed

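The data are 26 libraries of 3' end messenger RNA sequencing from mouse mammary fat pad fibroblasts (12 libraries) and bone-marrow-derived macrophages (14 libraries). Per the labels, fibroblasts came from 2 BALB/c females per replicate and were expanded, and macrophages were grown from bone marrow for 7 days in medium with 20% L929-conditioned medium. Cells were seeded at 300000 on collagen I, and 10000 fibroblasts were sorted per library. The submitters' processing notes name bcl2fastq, STAR 2.4.2a, HTSeq and the build mm10, without roles or order.

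The authors deposited raw counts of reads per gene for macrophages, and a normalized signal per gene for both cell types. In both normalized tables every value, multiplied by 1 size factor per library, gives a whole number of reads within 0.001 reads. For macrophages the authors' factor equals the median-of-ratios size factor of the deposited counts. There are 12948 genes listed for fibroblasts and 11822 for macrophages, with 11120 in both, and every listed gene has at least 6 reads in 1 library. Genes with fewer reads are therefore not covered. Reads were not realigned, and raw sequences were not used here.

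Libraries were grouped by cell type, culture and medium from the labels. The 3 macrophage columns headed DMEM without a partner were taken as the day 0 samples, the only macrophage group left without columns. The fibroblast comparisons were co-culture against mono-culture in each medium, 4T1 CM against DMEM in each culture, and the interaction of both. The macrophage comparisons were co-culture against mono-culture in 4T1 CM, 4T1 CM against DMEM in co-culture, co-culture in DMEM and mono-culture in 4T1 CM against day 0, and these last groups against each other. No macrophage sample is titled as a mono-culture in DMEM, so with this matching the co-culture effect in macrophages has no value in DMEM. If the column heads are right, the comparison of co-culture in DMEM with these 3 libraries is that effect.

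All calculations ran in R 4.3.3. Fibroblasts were tested with limma 3.58.1 (trend, moderated two-sided test) on log2 of the authors' normalized value plus a pseudocount of 1, for genes with at least 5 in at least 2 libraries (12401 genes), with the 12 libraries in 1 fit. Macrophages were tested with the edgeR 4.0.16 quasi-likelihood test on raw counts (TMM factors, filterByExpr, 10088 genes), with the 14 libraries in 1 fit. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. A group of 2 libraries borrows its spread from the others. A value of 0 in every library of a group was set to a floor of 3 reads over the group for fold bounds.

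From 33 gene lists written before the data were examined, those with at least 5 measured members were tested with camera in limma at a preset inter-gene correlation of 0.01. This made 140 tests in fibroblasts and 135 in macrophages, adjusted within each cell type. Macrophage lists used log2 CPM (reads of a gene scaled to a common library total) with a prior count of 2. Partner-enriched genes have a mean CPM at least 4 times higher in the other cell type's mono-culture or day 0 libraries. The partner share of a library is the median, over the marker genes of the partner, of the gene's level in percent of its mean level in the partner sorted from co-cultures in the same medium. It used 26 macrophage and 21 fibroblast markers.

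Genes were named by a rule. For each comparison of 2 groups it takes genes with adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 20 in the higher group, no overlap between the groups' libraries and a named symbol. It takes the 8 largest rises and falls, and 6 each way after leaving out partner-enriched genes. For the interaction and the last macrophage comparison it takes 5 each way without the condition on overlap. It adds up to 4 members of each list with the smallest adjusted p. Genes of ligands and receptors of both cell types, Adgre1 and Itgam could be named in every comparison. Gene positions come from GENCODE vM21 on mm10.

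Depth was 1945980 to 7632366 reads per fibroblast library and 1434695 to 4140985 per macrophage library. The tests were run on simulated data with 100 genes changed 2-fold and 100 changed 4-fold per comparison. The changed genes were drawn only from those above a minimum mean read count, so recovery at lower counts was not measured. No partner RNA was simulated. For 4-fold changes they recovered 93 in fibroblast co-culture in DMEM, 91 in that in 4T1 CM, 90 and 94 for 4T1 CM in mono-culture and co-culture, and 75 for the interaction. For 2-fold changes they recovered 54, 45, 37, 58 and 10 in the same order. In macrophages they recovered 97 or 98 of the 4-fold and 65 to 69 of the 2-fold changes.

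Alternatives fixed before the data were examined were other pseudocounts and filters, quantile normalization, TMM or median-of-ratios factors, the replicate number as a block, DESeq2 1.42.0, edgeR on recovered fibroblast reads, only the compared groups in the fit, no partner-enriched genes, a minimum fold, and each replicate left out in turn. Alternatives chosen after seeing the data were leaving out fibroblast co-cultures in 4T1 CM 3 and 4, and subtracting an estimated partner part. Lists of glial and muscle genes, which share no gene with the lists fixed in advance, were also chosen after seeing the data. Lists with fewer than 5 measured members were not tested.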

Results

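RNA was measured by 3' end sequencing of messenger RNA in 26 libraries from mouse cells grown in culture. Of these, 12 libraries came from mammary fat pad fibroblasts of BALB/c mice and 14 from bone-marrow-derived macrophages of the same strain. The cells were grown on collagen I, each type alone (mono-culture) or both together (co-culture). The medium was DMEM or medium conditioned by 4T1 cells, a mouse mammary carcinoma line (4T1 CM). After 7 days the co-cultures were sorted, fibroblasts as cells negative for F4/80 and CD11b and macrophages as cells positive for both; these antigens are the products of Adgre1 and Itgam. The fibroblast groups were co-culture in 4T1 CM (n = 4), co-culture in DMEM (n = 3), mono-culture in 4T1 CM (n = 2) and mono-culture in DMEM (n = 3). The macrophage groups were co-culture in 4T1 CM (n = 4), co-culture in DMEM (n = 3), mono-culture in 4T1 CM (n = 4) and macrophages at day 0 (n = 3). The day on which mono-cultures were harvested is not given in the sources used here, so co-culture and mono-culture may also differ in time. The columns of the day 0 macrophages are headed DMEM in the count table, and were matched to the day 0 samples by elimination. If the heads are right instead, the comparisons with day 0 below are those of co-culture in DMEM and of 4T1 CM in mono-culture.

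Depth ranged from 1945980 to 7632366 reads per fibroblast library and from 1434695 to 4140985 per macrophage library. The lowest fibroblast depth was in a mono-culture in DMEM, and the lowest macrophage depth in a co-culture in 4T1 CM. Gene values are read counts divided by the authors' size factor per library, given as mean ± SD over the libraries of a group. Changes are log2 fold changes ± SE from limma for fibroblasts and edgeR for macrophages, with adjusted p over 12401 and 10088 genes tested. Whether the cultures of different groups came from the same mice is not given in the sources used here. The p-values measure only the spread between these libraries. The groups, contrasts, tests, gene lists and rule for naming genes were fixed before the data were examined. Floors for values of 0 cover counting error only.

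Transcripts of partner marker genes were measured in every library. The partner share is the median level of the partner's marker genes in percent of their level in the sorted partner cells. In fibroblasts, the macrophage share was 1.23% ± 0.542 (SD, n = 3) in co-cultures in DMEM and 0.0244% ± 0.0141 (n = 3) in mono-cultures in DMEM. It was 0.202% ± 0.23 (n = 4) in co-cultures in 4T1 CM and 0.172% ± 0.029 (n = 2) in mono-cultures in that medium. Mono-cultures and day 0 libraries had no partner added, so their values are taken as the background. Co-cultures in 4T1 CM 3 and 4 (0.0127% and 0.0169%) were below that of mono-cultures in 4T1 CM (0.192% and 0.151%). In macrophages, the fibroblast share was 8.59% ± 8.27 (n = 4) in co-cultures in 4T1 CM, with replicate 3 at 20.8%. It was 3.55% ± 2.65 (n = 3) in co-cultures in DMEM, 0.0689% ± 0.0876 (n = 4) in mono-cultures in 4T1 CM and 0.043% ± 0.00829 (n = 3) at day 0. Genes at least 4 times higher in the mono-cultured or day 0 cells of the other type are called partner-enriched here. They number 662 of the genes tested in fibroblasts and 932 of those tested in macrophages.

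**Figure D1:**
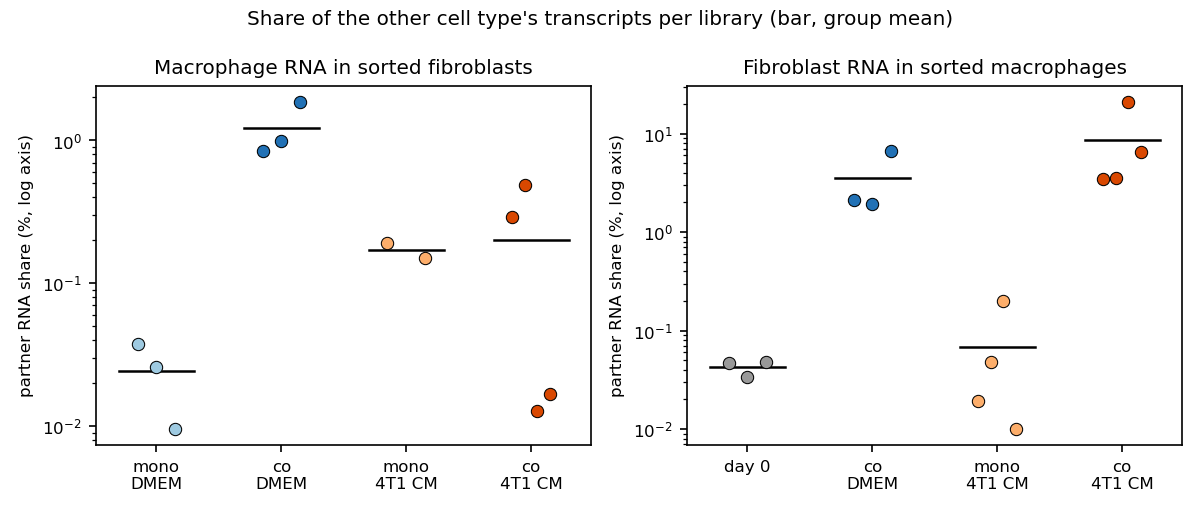
Partner share of each library, in percent on a log axis, by group; points are libraries and bars are group means. Macrophages co-cultured in 4T1 CM carried 3.44% to 20.8% and fibroblasts co-cultured in DMEM 0.845% to 1.85%.

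**Figure D2:**
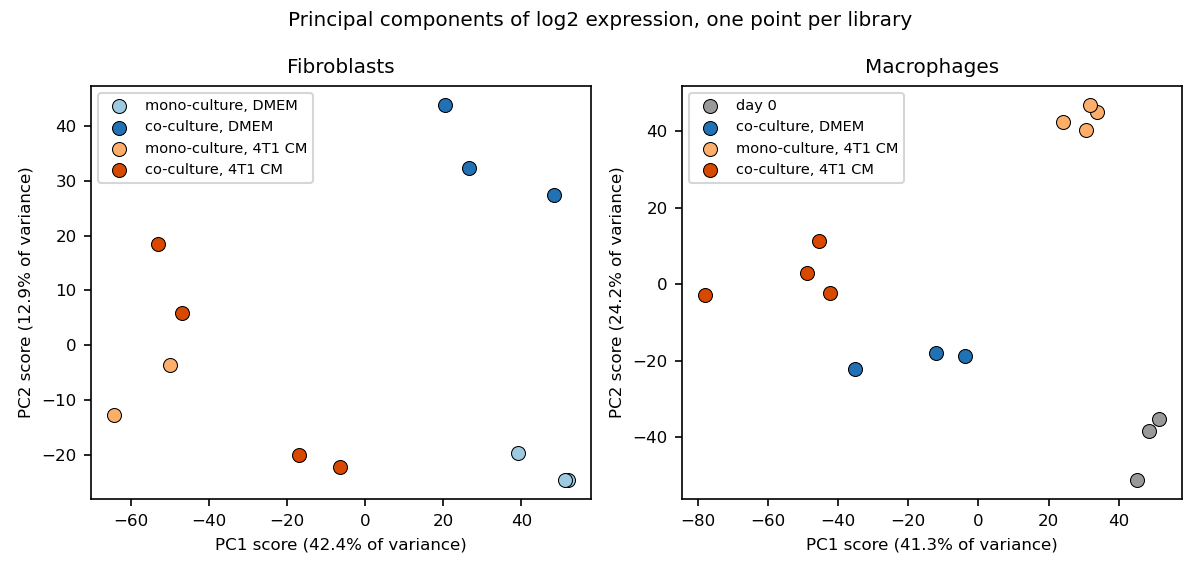
First and second principal components of the fibroblast libraries (42.4% and 12.9% of the variance on the axes) and of the macrophage libraries (41.3% and 24.2%), coloured by group. Fibroblast co-cultures in 4T1 CM 1 and 2 lie at -46.8 and -53.1 on the first component, and co-cultures 3 and 4 at -17 and -6.4.

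The first comparison asked what 4T1 CM does to fibroblasts grown without macrophages. Genes of inflammation rose, among them Cxcl3 and Cxcl5, chemokines that attract neutrophils, and Nos2, which makes nitric oxide. Serpinb2, an inhibitor of plasminogen activators, Lcn2 and Saa3, proteins of the acute phase, and C3, the central complement component, rose with them. So did Mmp9, Tnc, Timp1 and Dcn. Actg2, Cnn1 and Eln fell together with Gas6, a ligand of TAM receptors, and the short-chain collagen gene Col8a1. Transcripts of Sox10 and Ngfr, typical of glial cells, and of Myl1 and Mybph, typical of skeletal muscle, were close to lost.

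Serpinb2 rose from 8.55 ± 12.6 normalized reads in mono-cultures in DMEM (n = 3) to 1730 ± 525 in mono-cultures in 4T1 CM (n = 2), a log2 change of 8.46 ± 1.2 (adjusted p = 0.000789). Nos2 rose from 2.39 ± 2.08 to 808 ± 359, and Lcn2 from 11.6 ± 9.99 to 531 ± 42.4. Cxcl3 went from 5.54 ± 3.25 to 507 ± 42 and Cxcl5 from 150 ± 50.2 to 3730 ± 906, with log2 changes of 6.43 ± 0.53 and 4.66 ± 0.39 (adjusted p = 2.33e-05 for both). Mmp9 rose by 6.61 ± 0.29 (adjusted p = 2.52e-08; 14.5 ± 2.38 to 1510 ± 295). Saa3, which is partner-enriched, reached 8420 ± 2910 from 109 ± 36.6, and C3 reached 808 ± 75.7 from 57.6 ± 11.9. Timp1, an inhibitor of metalloproteinases, rose from 4980 ± 363 to 18200 ± 1080, Tnc from 1400 ± 100 to 5710 ± 1050 and Dcn from 2820 ± 828 to 12700 ± 2810. Serpinb2 lies on chromosome 1 from 107511423 to 107535478, Lcn2 on chromosome 2 from 32384633 to 32388252 and Cxcl3 on chromosome 5 from 90786103 to 90789600 (mm10, GENCODE vM21).

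Among the falls, Sox10 dropped from 533 ± 62.2 to 0.987 ± 1.4 (log2 change -8.27 ± 1.21, adjusted p = 0.000938) and Ngfr from 764 ± 84.3 to 1.24 ± 1.75. Sox10 lies on chromosome 15 from 79154908 to 79165240. Myl1 fell from 339 ± 329 (164, 719 and 135 in the 3 libraries) to 1.4 ± 0.813 (log2 change -6.76 ± 0.7, adjusted p = 0.000106). Mybph had 133 ± 135 in DMEM and no read in either library in 4T1 CM, at least 76.2-fold lower against a floor of 3 reads over the group. Without mono-culture in DMEM 2 its mean in DMEM was 55.1 and the bound 31.6-fold. Gas6 fell from 4220 ± 923 to 237 ± 19 (log2 change -4.13 ± 0.61, adjusted p = 0.000939) and Col8a1 from 567 ± 71.2 to 45.1 ± 3.17. Actg2 fell from 265 ± 77.8 to 16.5 ± 12.9, Cnn1 from 651 ± 239 to 132 ± 23, and Ccn3 from 2920 ± 330 to 20.8 ± 4.35. Eln fell from 46.7 ± 2.53 to 0.825 ± 1.17 (adjusted p = 0.00357, 0.0556 without mono-culture in 4T1 CM 1).

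By limma, 1648 genes differed, 789 higher and 859 lower in 4T1 CM; an unadjusted p under 0.05 was reached by 3554. Leaving out mono-culture in 4T1 CM 1 gave 535 genes, leaving out mono-culture in DMEM 1 gave 849 and mono-culture in DMEM 2 gave 1073. Of the genes fixed as NF-kB and acute-phase genes, 11 of 20 rose, 15 with 1 fall when adjusted over the list alone (list adjusted p = 4.67e-09 by camera with a preset correlation, 0.128 with an estimated correlation). Of the cytokine and chemokine genes, 11 of 23 rose and 2 fell, and 12 and 3 when adjusted over the list alone (adjusted p = 5e-05, 0.132 with an estimated correlation). Interferon-response genes rose in 7 of 31 cases, 5 of them not partner-enriched (8 adjusted over the list alone; adjusted p = 0.000767, 0.62 with an estimated correlation) and genes of MHC class I presentation, such as H2-K1 and Psmb8, in 5 of 14, 1 of them not partner-enriched (8 adjusted over the list alone; adjusted p = 0.00137, 0.416). Of 25 macrophage marker genes, all partner-enriched, 2 rose (2 adjusted over the list alone; adjusted p = 0.00105, 0.594). H2-K1 rose from 767 ± 29.3 to 2120 ± 369. Of 35 cell-cycle genes, 7 rose, Mcm6 among them (10 adjusted over the list alone; adjusted p = 0.000643, 0.572 with an estimated correlation). Of 22 contractile genes 8 fell and 2 rose, 8 and 3 when adjusted over the list alone, and the list was not called (adjusted p = 0.0739, 0.652). Of 29 collagen and matrix genes 7 rose and 6 fell, 9 and 7 when adjusted over the list alone, and the list was not called either (adjusted p = 0.561, 0.863). Csf1, the growth factor that macrophages depend on, did not pass (log2 change 0.61, adjusted p = 0.0567), but did with quantile normalization (0.0472) and on recovered reads with edgeR (0.0499) or DESeq2 (0.0172). Transcripts of its receptor gene Csf1r were higher, 122 ± 24 against 19.7 ± 1.54 (log2 change 2.56 ± 0.34, adjusted p = 0.000537).

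The second comparison asked what 4T1 CM does to fibroblasts grown together with macrophages. The chemokine genes Cxcl3 and Cxcl5 rose here too, with Lcn2, Il6 and Spp1, the gene of osteopontin. Mmp3, Mmp9 and Mmp10 rose with them, and so did the haem-degrading enzyme gene Hmox1, the growth factor genes Fgf7 and Csf1, and Cebpb, a transcription factor of acute-phase genes. Genes of endothelium, Pecam1, Cdh5 and Plvap, fell, as did matrix genes such as Col14a1, Fndc1 and Eln. The partner-enriched genes Fcrls, Apoe and C1qb fell as well, in cells whose macrophage share was 0.202% in 4T1 CM against 1.23% in DMEM.

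Lcn2 rose from 16.3 ± 8.66 in co-cultures in DMEM (n = 3) to 453 ± 196 in co-cultures in 4T1 CM (n = 4), a log2 change of 4.79 ± 0.55 (adjusted p = 0.000331). Cxcl3 rose by 4.32 ± 0.44 (adjusted p = 0.000132; 16.1 ± 8.12 to 349 ± 171) and Cxcl5 from 256 ± 71.9 to 2370 ± 1110. Mmp3 went from 116 ± 82.3 to 1350 ± 451 and Mmp9 from 121 ± 10.2 to 917 ± 379. Il6 rose from 13.4 ± 4.89 to 74.8 ± 27.7, Spp1 from 4170 ± 2300 to 21000 ± 3560, and Fgf7 from 247 ± 26.8 to 971 ± 140. Hmox1 rose from 969 ± 151 to 3600 ± 378 (log2 change 1.9 ± 0.18, adjusted p = 9.34e-05) and Cebpb from 1270 ± 215 to 3220 ± 465. Csf1, on chromosome 3 from 107741048 to 107760469, rose from 5200 ± 1180 to 8650 ± 494 (log2 change 0.76 ± 0.17, adjusted p = 0.0153, 0.0797 without co-culture in DMEM 1). Mmp13 rose from 1.44 ± 1.57 to 37.5 ± 34.2 (adjusted p = 0.0112, 0.0689 without co-culture in DMEM 1). Serpinb2 rose by 4.7 ± 1 (adjusted p = 0.0141), and did not pass without co-culture in DMEM 1 (0.071) or 3 (0.0518).

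Pecam1 fell from 49.6 ± 32.5 to 1.46 ± 1.97 (log2 change -4.53 ± 0.67, adjusted p = 0.00166), Cdh5 from 33 ± 30.4 to 0.522 ± 1.04 and Plvap from 103 ± 69 to 8.01 ± 6.36. Col14a1 fell from 195 ± 152 to 6.6 ± 4.72, Fndc1 from 288 ± 223 to 13.8 ± 9.7 and Eln from 89.1 ± 87.5 to 2.39 ± 2.2. Apoe fell from 3340 ± 1320 to 361 ± 119 and Fcrls from 61 ± 23.4 to 0.676 ± 0.82. C1qb fell from 295 ± 170 to 22.2 ± 24.2 (adjusted p = 0.0136, 0.0562 without co-culture in DMEM 3). Pdgfb, a partner-enriched gene for a growth factor of mesenchymal cells, fell from 86.1 ± 23.3 to 4.44 ± 2.08.

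By limma, 725 genes differed, 289 higher and 436 lower in 4T1 CM, and 96 of the lower ones were partner-enriched. Leaving out co-culture in DMEM 1 gave 264 genes and co-culture in 4T1 CM 1 gave 470. An unadjusted p under 0.05 was reached by 2370 genes. Of the NF-kB and acute-phase genes 9 of 20 rose (9 adjusted over the list alone; adjusted p = 1.17e-07, 0.132 with an estimated correlation). Of 23 cytokine and chemokine genes 9 rose, 10 with 3 falls when adjusted over the list alone (adjusted p = 9.82e-05, 0.132). Of 29 collagen and matrix genes 11 fell and 4 rose, 13 and 4 when adjusted over the list alone (adjusted p = 0.0157, 0.443). Of 13 endothelial genes 7 fell (7 adjusted over the list alone; adjusted p = 6.97e-07, 0.132), and of 6 mural-cell genes 3, Cspg4 among them (5 adjusted over the list alone; adjusted p = 0.000364, 0.128). Of 25 protease and inhibitor genes 8 rose and 3 fell, 9 and 7 when adjusted over the list alone, and the list was not called (adjusted p = 0.213, 0.416). Of 19 genes of the oxidative stress response 3 rose (6 adjusted over the list alone; adjusted p = 4.99e-05, 0.16). The list of 35 cell-cycle genes was not called (adjusted p = 0.822); 0 of its members passed by limma, 0 had an unadjusted p under 0.05, and 0 passed by edgeR or by DESeq2 on recovered reads.

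**Figure D3:**
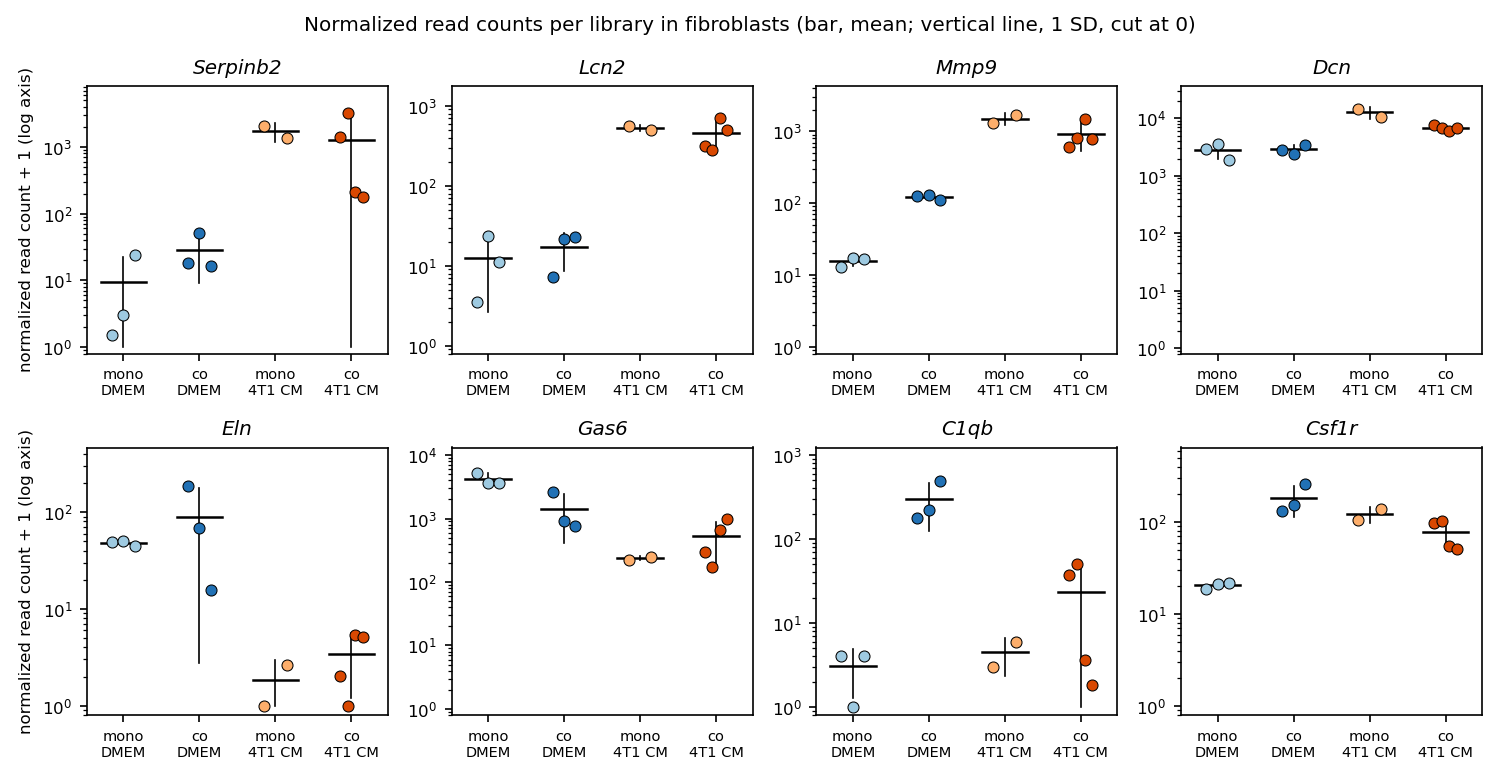
Normalized reads plus 1 on a log axis for 8 genes in the 12 fibroblast libraries, by group; points are libraries, bars are means and vertical lines 1 SD, not drawn under 0. Serpinb2, Lcn2 and Mmp9 are higher in 4T1 CM than in DMEM, Dcn also, and Csf1r was 19.7 in mono-cultures in DMEM against 181 in co-cultures in DMEM.

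The response to 4T1 CM was set side by side in mono-cultures and co-cultures. Cxcl3, Cxcl5, Lcn2, Mmp9, Dcn, Timp1 and Tnc rose in both, and Ccn3, Eln and Col8a1 fell in both. Across 12401 genes the log2 changes had a Pearson correlation of 0.593 and a Spearman correlation of 0.471; genes are not independent replicates. Both comparisons called 186 genes higher, against 18.4 by chance, and 243 lower, against 30.2, while 4 went opposite ways. The slope of the co-culture change on the mono-culture change was 0.418 over all genes, a value that noise in the mono-culture change lowers. In genes called in both, the median absolute log2 change was 2.013 in mono-culture and 1.643 in co-culture.

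The third comparison set fibroblasts co-cultured with macrophages in DMEM beside mono-cultures in DMEM, which may also differ in harvest day. Most genes that rose are macrophage genes: the complement gene C1qb, the lysozyme gene Lyz2, the lipid carrier gene Apoe, Trem2, Fcrls, and Csf1r and Adgre1. These are partner-enriched, in cells that carried a macrophage share of 1.23%. Beyond them, Mmp9, C3 and Bend5 rose, with Serpina3g, an inhibitor of serine proteases, and Notch3, a marker gene of mural cells. The list of mural-cell markers was called higher with a preset correlation (adjusted p = 0.000572) but not with an estimated one (0.128). The metalloproteinase genes Mmp13 and Mmp11 fell, and so did Hmox1.

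Fcrls rose from 0.171 ± 0.295 in mono-cultures (n = 3) to 61 ± 23.4 in co-cultures (n = 3), a log2 change of 5.69 ± 0.55 (adjusted p = 0.000427). Trem2 rose from 1.37 ± 1.29 to 79.8 ± 25.3, Apoe from 601 ± 202 to 3340 ± 1320 and Adgre1 from 0.682 ± 1.18 to 43.7 ± 16.5. C1qb, on chromosome 4 from 136880129 to 136886187, rose from 2.05 ± 1.77 to 295 ± 170 (log2 change 6.71 ± 1.06, adjusted p = 0.0122; 0.0709 without co-culture in DMEM 3 and 0.0534 without mono-culture in DMEM 2). Lyz2 rose from 48.9 ± 10.6 to 2360 ± 933 (adjusted p = 0.0122), and did not pass without co-culture in DMEM 2 (0.0548) or 3 (0.0709) or mono-culture in DMEM 1 (0.0611) or 3 (0.0664). Itgam did not pass (log2 change 4.15 ± 0.99, adjusted p = 0.0737), but did with a pseudocount of 5 (0.0231) or only the 2 compared groups in the fit (0.00415). Csf1r, on chromosome 18 from 61100598 to 61132149, rose from 19.7 ± 1.54 to 181 ± 67.9 (log2 change 3.08 ± 0.31, adjusted p = 0.000427).

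Outside the partner-enriched genes, Mmp9 rose by 2.99 ± 0.26 (adjusted p = 0.000194; 14.5 ± 2.38 to 121 ± 10.2) and C3 by 2.68 ± 0.39 (adjusted p = 0.00725; 57.6 ± 11.9 to 431 ± 292). Serpina3g rose from 28.9 ± 9.92 to 161 ± 30.7 (adjusted p = 0.00995, 0.0535 without mono-culture in DMEM 1). Notch3 rose from 70.3 ± 11.2 to 211 ± 44.6 (adjusted p = 0.0148), and did not pass without co-culture in DMEM 2 (0.0638) or mono-culture in DMEM 2 (0.0665) or 3 (0.0664). Mmp11 fell from 1650 ± 22.7 to 666 ± 84.3 (log2 change -1.32 ± 0.22, adjusted p = 0.0148), and did not pass without co-culture in DMEM 2 (0.0604) or any mono-culture in DMEM (0.0627, 0.0526 and 0.0664). Mmp13, on chromosome 9 from 7272514 to 7283331, fell from 40.1 ± 41.2 to 1.44 ± 1.57 (adjusted p = 0.0427), and did not pass without any single library (0.0687 to 0.218). Hmox1 fell by 1.16 on the log2 scale, and did not pass without co-culture in DMEM 3 (0.0928) or mono-culture in DMEM 1 (0.0694) or 3 (0.0699).

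By limma, 124 genes differed, 106 higher and 18 lower in co-culture, and 68 of the higher ones were partner-enriched; 1351 genes had an unadjusted p under 0.05. Leaving out any single library gave 18 to 81 genes, and 13 of the 124 were called each time. The counts were 18, 34 and 26 without mono-cultures in DMEM 1, 2 and 3, and 81, 28 and 21 without co-cultures in DMEM 1, 2 and 3. Of 25 macrophage marker genes 19 rose (24 adjusted over the list alone; adjusted p = 1.07e-34, 0.128 with an estimated correlation), and of 15 complement and Fc receptor genes 10, 1 of them not partner-enriched (12 adjusted over the list alone; adjusted p = 1.66e-13, 0.128). Of 6 mural-cell genes 2 rose (2 adjusted over the list alone; adjusted p = 0.000572, 0.128). Lists of 13 endothelial (adjusted p = 0.000226, 0.216) and 7 epithelial genes (0.00937, 0.397) were called higher with 6 and 1 members passing when adjusted over the list alone. Over all genes 0 of these passed by limma, with 7 and 2 at an unadjusted p under 0.05, and 0 by edgeR or by DESeq2 on recovered reads. Hypoxia genes were called higher as a list with 1 of 20 members passing (8 adjusted over the list alone; adjusted p = 5e-05, 0.216). The list of 29 collagen and matrix genes was not called (adjusted p = 0.124). By limma 0 of them passed and 5 had an unadjusted p under 0.05, and 0 passed by edgeR or by DESeq2 on recovered reads.

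The fourth comparison was the same in 4T1 CM. Only skeletal muscle genes passed: Mybph, which encodes a myosin-binding protein, Myl1, a myosin light chain gene, and Mymk, which drives the fusion of myoblasts. Col1a1, Dcn and Csf1, genes of the fibroblast's own matrix and of its signal to macrophages, did not pass. The macrophage share was 0.202% in these co-cultures and 0.172% in the mono-cultures.

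Mybph had 28.4 ± 11.4 in co-cultures (n = 4) and no read in either mono-culture (n = 2), at least 16.3-fold higher against a floor of 3 reads over the group (adjusted p = 0.023). Myl1 had 60.3 ± 35.7 against 1.4 ± 0.813 (log2 change 4.51 ± 0.67, adjusted p = 0.0486). Mymk had 19.2 ± 7.19 against no read in either mono-culture (adjusted p = 0.0486); its mean is below the minimum of the naming rule, and it was chosen after its values were seen. Mybph, on chromosome 1 from 134193448 to 134201232, did not pass without mono-culture in 4T1 CM 1 (0.685) or without co-culture 2 (0.0872), 3 (0.0853) or 4 (0.0933). Myl1 did not pass without these libraries either (0.0876 to 0.689), and Mymk also not without co-culture 1 (0.0543). Dcn had 6780 ± 664 in co-cultures and 12700 ± 2810 in mono-cultures (adjusted p = 0.311), Col1a1 6250 ± 450 and 10700 ± 1280 (adjusted p = 0.282, 0.0174 by DESeq2 on recovered reads), and Csf1 8650 ± 494 and 6700 ± 1140 (adjusted p = 0.559).

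By limma, 3 genes differed, all higher in co-culture, and 1155 had an unadjusted p under 0.05. Without mono-culture in 4T1 CM 2 the count was 296, with the lone remaining mono-culture assumed to vary like the other groups, and without mono-culture 1 or any of co-cultures 2, 3 and 4 it was 0. Collagen and matrix genes were called lower as a list (adjusted p = 0.0117, 0.437 with an estimated correlation), with 5 of 29 falling and 1 rising when adjusted over the list alone. Over all genes 0 of the 29 passed by limma (9 at an unadjusted p under 0.05), 0 by edgeR and 2 by DESeq2 on recovered reads. Fibroblast marker genes were called lower (adjusted p = 0.0358, 0.445) and genes of cholesterol synthesis higher (adjusted p = 0.00322, 0.445). Of 23 fibroblast markers and 22 cholesterol genes 0 passed by limma, with 5 and 3 at an unadjusted p under 0.05, 0 and 0 passed by edgeR, and 1 and 0 by DESeq2. The co-culture changes in DMEM and in 4T1 CM had a Pearson correlation of -0.102 and a Spearman correlation of -0.094 across genes, which are not independent replicates. No gene was called in both, but chance gives only 0.0256 higher in both, so this overlap cannot show a difference between media.

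The interaction of partner and medium tested whether the co-culture change differed between media. Genes of macrophages, Csf1r, Trem2, Cybb and Fcrls, and the matrix protease gene Mmp9 had a lower co-culture change in 4T1 CM than in DMEM. Hmox1, an antioxidant gene, and Mybph had a higher one. By limma 18 genes differed, 4 with a higher and 14 with a lower co-culture change in 4T1 CM, and 7 of the lower ones were partner-enriched; 1508 had an unadjusted p under 0.05. Csf1r differed by -3.81 ± 0.45 (adjusted p = 0.00462), Mmp9 by -3.77 ± 0.37 (adjusted p = 0.00115) and Hmox1 by 1.65 ± 0.28 (adjusted p = 0.0342). Hmox1 had 3600 and 2580 normalized reads in co-culture and mono-culture in 4T1 CM and 969 and 2200 in DMEM. The count was 197 without mono-culture in 4T1 CM 2 and 73 without co-culture in 4T1 CM 2. It was 2 without mono-culture in 4T1 CM 1, mono-culture in DMEM 1 or 3 or co-culture in DMEM 2, 4 without co-culture in DMEM 1 or 3, and 8 without mono-culture in DMEM 2. Csf1r and Mmp9 passed without each library in turn. With the replicate number as a block in limma, Csf1r did not pass (-3.64, adjusted p = 0.0505). Trem2, Cybb, Fcrls, Hmox1 and Mybph did not pass without any 1 of the co-cultures in DMEM, mono-cultures in DMEM 1 and 3 and mono-culture in 4T1 CM 1. Without the last of these their adjusted p were 0.219, 0.238, 0.158, 0.129 and 0.208. Trem2, Cybb and Fcrls also did not pass without mono-culture in DMEM 2, Cybb, Hmox1 and Mybph without co-culture in 4T1 CM 3, and Cybb and Hmox1 without co-culture 4.

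In macrophages, the first comparison asked what happens between day 0 and mono-culture in 4T1 CM, where time and medium differ together. Seeding on collagen I may differ too. Acute-phase and inflammatory genes rose, among them Saa3, Slpi, Il1b and Socs3, a feedback inhibitor of cytokine signals. Mmp8, a neutrophil collagenase gene, Ly6a, Clec4n, the complement genes C1qa and Cfp and the Fc receptor gene Fcgr2b rose too. Genes of cell division, such as Top2a, Bub1b, Birc5 and Pbk, were close to lost. Pparg, a regulator of lipid genes, its target Cd36 and the integrin gene Itgax fell.

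Saa3 rose from 164 ± 98.4 at day 0 (n = 3) to 34000 ± 7630 in mono-culture in 4T1 CM (n = 4), a log2 change of 7.72 ± 0.51 (adjusted p = 4.08e-08). Slpi rose from 20.3 ± 7.47 to 2110 ± 743, Il1b from 13.5 ± 3.21 to 948 ± 612, Ly6a from 15 ± 11.3 to 2940 ± 497 and Clec4n from 78.5 ± 25.7 to 4230 ± 990. Mmp8 rose from 84 ± 10.5 to 1420 ± 321, and C1qa from 2250 ± 322 to 16100 ± 2560. Top2a fell from 613 ± 294 to 12.2 ± 2.51 (log2 change -5.58 ± 0.39, adjusted p = 5.82e-08) and Birc5 from 356 ± 184 to 5.08 ± 2.57. Bub1b had 116 ± 46.3 at day 0 and no read in the 4 mono-cultures, at least 152-fold lower against a floor of 3 reads over the group. Pparg fell from 87.1 ± 8.52 to 2.65 ± 1.27, Cd36 from 183 ± 44.1 to 5.46 ± 2.8 and Itgax from 476 ± 133 to 16.1 ± 7.91.

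By edgeR, 2214 genes differed, 1116 higher and 1098 lower than at day 0. Of 13 genes of alternative activation 7 rose and 2 fell, as many when adjusted over the list alone (camera adjusted p = 0.000116, 0.06 with an estimated correlation). All 30 cell-cycle genes fell (30 adjusted over the list alone; adjusted p = 3.7e-34 by camera, 0.0647 with an estimated correlation). Of 18 complement and Fc receptor genes 13 rose and 1 fell, as many when adjusted over the list alone (adjusted p = 2.56e-07), and this list was called with an estimated correlation too (0.0412). Of 16 NF-kB and acute-phase genes 10 rose (10 adjusted over the list alone; adjusted p = 2.92e-06, 0.112), and of 13 genes of MHC class I presentation 7 (9 adjusted over the list alone; adjusted p = 0.000486, 0.154). Among genes of MHC class II presentation, H2-Ab1 rose from 2780 ± 1830 to 10400 ± 3480, and 2 of 8 passed (7 adjusted over the list alone; adjusted p = 0.00921, 0.417).

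The next comparison followed macrophages from day 0 to co-culture with fibroblasts in DMEM, where time and partner differ together. The chemokine genes Ccl8 and Ccl12 rose, with F13a1 and Mrc1, genes of alternative activation, and with Socs3, Saa3 and Lrg1. C1qa, Spp1, Gas6 and the glycolysis gene Eno2 rose as well. Genes of antigen presentation on MHC class II, H2-Aa, H2-Ab1 and Cd74, fell, together with Itgax, Pparg and the lipase gene Mgll. Fibroblast genes such as Fmod and Prelp rose in cells with a fibroblast share of 3.55%.

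Ccl8 rose from 1.46 ± 0.661 at day 0 (n = 3) to 969 ± 756 in co-culture (n = 3), a log2 change of 9.26 ± 1.03 (adjusted p = 1.58e-05). Lrg1 rose from 1.01 ± 1.15 to 299 ± 95, F13a1 from 26.6 ± 12.6 to 1570 ± 554 and Mrc1 from 323 ± 33.6 to 1600 ± 392. Spp1 rose from 3260 ± 643 to 27700 ± 10200, C1qa from 2250 ± 322 to 18600 ± 1400, Gas6 from 1540 ± 288 to 4200 ± 161 and Eno2 from 231 ± 61.8 to 719 ± 139. H2-Aa, on chromosome 17 from 34282744 to 34287823, fell from 3740 ± 2310 to 72.9 ± 64.7 (log2 change -5.71 ± 0.75, adjusted p = 7.71e-05). H2-Ab1 fell from 2780 ± 1830 to 128 ± 56.4 and Cd74 from 5180 ± 2770 to 233 ± 180. Itgax fell from 476 ± 133 to 22.8 ± 9.9, Pparg from 87.1 ± 8.52 to 5.91 ± 3.47 and Mgll from 74.4 ± 19.3 to 0.613.

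By edgeR, 1531 genes differed, 854 higher and 677 lower, and 341 of the higher ones were partner-enriched. Leaving out co-culture in DMEM 3 gave 984 genes. All 8 genes of MHC class II presentation fell (8 adjusted over the list alone; adjusted p = 1.14e-09, 0.105 with an estimated correlation). The lists that were called with an estimated correlation too were alternative activation, with 9 of 13 higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 1.63e-08, 0.0262), glycolysis, with 13 of 18 higher (14 adjusted over the list alone; 1.44e-13, 0.0412), and hypoxia, with 13 of 20 higher (15 adjusted over the list alone; 2.58e-13, 0.0412). Of these risers, 9 glycolysis and 5 hypoxia genes are not partner-enriched. Of 16 proinflammatory macrophage genes 6 rose, 10 with 1 fall when adjusted over the list alone (camera adjusted p = 0.000206, 0.086 with an estimated correlation). Of 30 cell-cycle genes 19 fell (28 adjusted over the list alone; adjusted p = 4.01e-09, 0.239), Pcna from 607 ± 256 to 274 ± 17, and of 33 interferon-response genes 14 fell (22 adjusted over the list alone; adjusted p = 1.11e-07, 0.239). All 25 collagen and matrix genes rose and all are partner-enriched (25 adjusted over the list alone; adjusted p = 8.66e-26, 0.0971).

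The co-culture effect on macrophages was measured in 4T1 CM, against mono-cultures whose harvest day may differ. Arg1, which consumes arginine and marks suppressive macrophages, rose with Spp1, F13a1 and the sheddase gene Adam8. Genes of cell division, Top2a, Ube2c, Ccnb2 and Birc5, rose, and so did Ankrd37, Eno2 and Pgam1, genes of hypoxia and glycolysis. Genes of antigen presentation on MHC class II, H2-Aa, H2-Ab1, H2-Eb1, Cd74 and their regulator Ciita, fell. Interferon-response genes, such as Isg15 and Oasl2, fell with Saa3, Aif1, Apoe, Igf1 and Csf1r, the receptor gene for Csf1. Fibroblast genes, among them Dcn, Fn1 and Csf1, rose in cells with a fibroblast share of 8.59%.

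Arg1, on chromosome 10 from 24915221 to 24927484, rose from 181 ± 134 in mono-cultures (n = 4) to 31400 ± 5530 in co-cultures (n = 4), a log2 change of 7.41 ± 0.87 (adjusted p = 1.65e-05). Spp1 rose from 1960 ± 540 to 19200 ± 2820, F13a1 from 394 ± 47.9 to 2840 ± 727 and Adam8 from 1440 ± 222 to 5540 ± 960. Top2a rose from 12.2 ± 2.51 to 107 ± 50.6 (log2 change 3.13 ± 0.39, adjusted p = 3.04e-05) and Ube2c from 1.91 to 92.5 ± 54.6. Eno2 rose from 354 ± 40.5 to 1090 ± 91.6 and Ankrd37 from 42.6 ± 11.2 to 324 ± 50.7. With an estimated fibroblast part subtracted, Birc5 (log2 change 1.81, adjusted p = 0.051) and Ccnb2 (2.53, 0.0696) did not pass. That fit used limma on log2 values in place of edgeR. Among partner-enriched genes, Dcn rose from 1.51 ± 3.02 to 662 ± 654 and Csf1 from 13.3 ± 4.21 to 421 ± 346.

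H2-Aa fell from 9450 ± 4070 to 65.3 ± 54.2 (log2 change -7.28 ± 0.7, adjusted p = 2.71e-06), H2-Eb1 from 6530 ± 1350 to 38 ± 39.7, Cd74 from 15000 ± 3380 to 298 ± 224 and Ciita from 23.2 ± 6.88 to 0.222. Saa3 fell from 34000 ± 7630 to 1610 ± 705, Isg15 from 361 ± 45.1 to 95.7 ± 18.9 and Oasl2 from 484 ± 74 to 111 ± 55.6. Csf1r fell from 12800 ± 1630 to 3330 ± 581 (log2 change -1.95 ± 0.19, adjusted p = 3.39e-06), Apoe from 172000 ± 25800 to 44600 ± 12100 and Aif1 from 988 ± 160 to 93.2 ± 30.4. Of the antigens of the sort, Adgre1 fell from 2400 ± 272 to 917 ± 199 and Itgam did not pass (2600 ± 561 against 2430 ± 257, adjusted p = 0.747).

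By edgeR, 2618 genes differed, 1415 higher and 1203 lower in co-culture; 617 of the higher ones and 3 of the lower ones were partner-enriched. All 25 collagen and matrix genes rose (25 adjusted over the list alone; adjusted p = 9.48e-21, 0.111 with an estimated correlation), as did 20 of 21 fibroblast markers (20 adjusted over the list alone; adjusted p = 8.82e-17, 0.108), and all of these risers are partner-enriched. Of 30 cell-cycle genes 27 rose (28 adjusted over the list alone; adjusted p = 2.43e-13, 0.162 with an estimated correlation). With an estimated fibroblast part subtracted 8 of them rose by limma, and 18 when co-culture in 4T1 CM 3 was also left out. Of 18 glycolysis genes 14 rose, 11 of them not partner-enriched (15 adjusted over the list alone; adjusted p = 5.91e-09, 0.0647), and of 20 hypoxia genes 16, 8 of them not partner-enriched (17 adjusted over the list alone; adjusted p = 5.71e-11, 0.0542). All 8 genes of MHC class II presentation fell (8 adjusted over the list alone; adjusted p = 1.69e-09, 0.105), as did 9 of 13 of MHC class I presentation (9 adjusted over the list alone; adjusted p = 8.43e-06, 0.0958). Of 33 interferon-response genes 25 fell (27 adjusted over the list alone; adjusted p = 1.8e-14, 0.108), and of 27 macrophage marker genes 17 fell and 1 rose (20 and 1 adjusted over the list alone; adjusted p = 3.89e-08, 0.111).

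**Figure D4:**
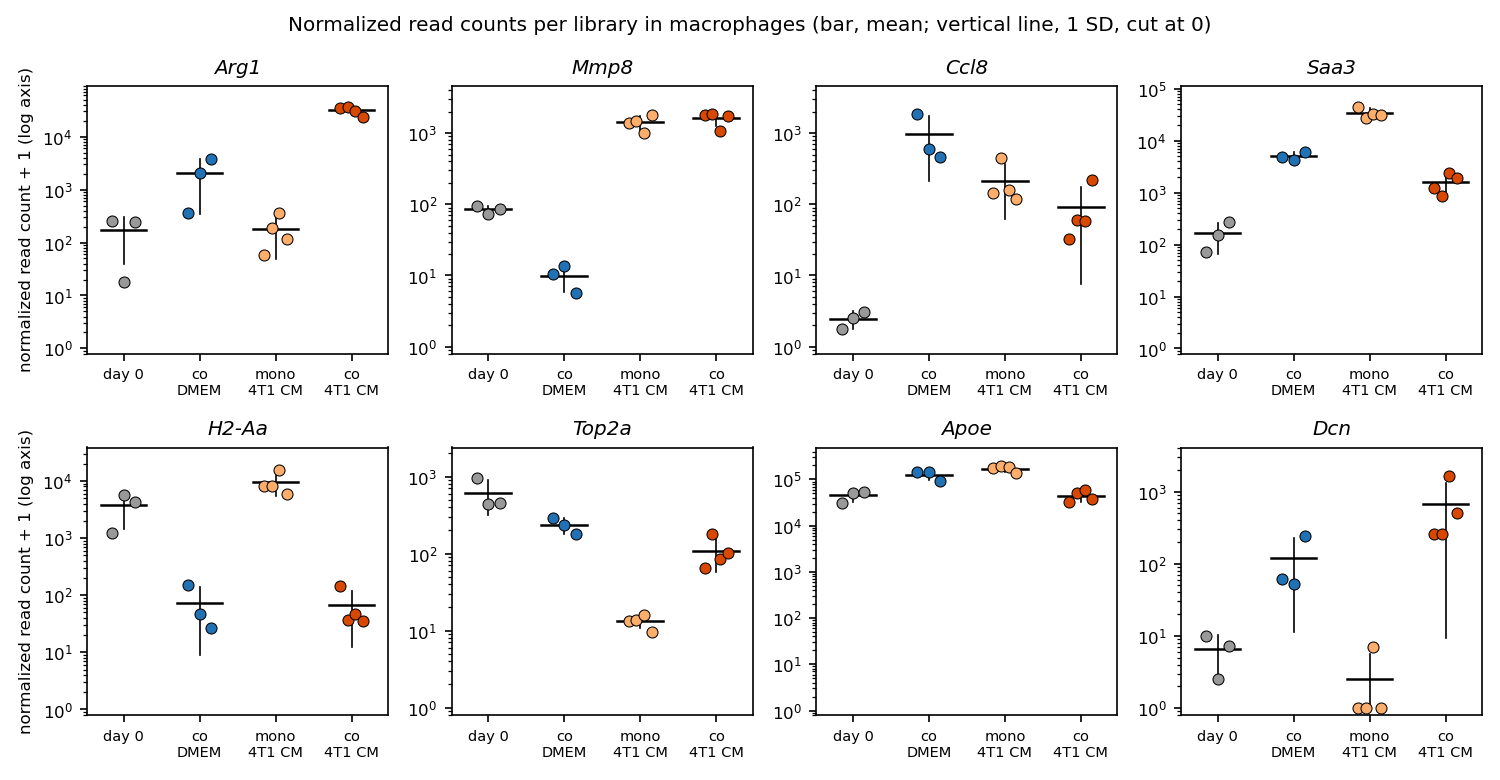
Normalized reads plus 1 on a log axis for 8 genes in the 14 macrophage libraries, by group; points are libraries, bars are means and vertical lines 1 SD, not drawn under 0. Arg1 averages 31400 in co-cultures in 4T1 CM against 181 in mono-cultures in that medium, and H2-Aa 65.3 against 9450.

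The effect of 4T1 CM was then measured in macrophages co-cultured with fibroblasts. The collagenase genes Mmp8 and Mmp13 rose, with Mmp19, the urokinase receptor gene Plaur, and F7, a coagulation factor gene. Arg1 rose, and so did Osm, a cytokine that acts on fibroblasts, Clec4n and the co-stimulatory gene Cd86. Fcrls, Cd5l, Igf1, C1qb and Apoe fell, and so did Csf1r, Adgre1 and Gas6. Genes of DNA replication, Mcm7 and Tk1, fell.

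Mmp8, on chromosome 9 from 7558456 to 7568485, rose from 8.93 ± 4.1 in DMEM (n = 3) to 1630 ± 365 in 4T1 CM (n = 4), a log2 change of 7.59 ± 0.35 (adjusted p = 1.76e-09). Mmp13 had 80 ± 67.1 in 4T1 CM and no read in DMEM, at least 88.4-fold higher against a floor of 3 reads over the group, or 51.7-fold without co-culture in 4T1 CM 4. Mmp19 rose from 179 ± 6.69 to 892 ± 214, Plaur from 97.5 ± 25.4 to 430 ± 30.6, Osm from 36.5 ± 8.29 to 129 ± 32.8 and Clec4n from 716 ± 325 to 3660 ± 997. Arg1 rose from 2090 ± 1740 to 31400 ± 5530 (log2 change 3.92 ± 0.82, adjusted p = 0.00523). Fcrls fell from 4140 ± 367 to 167 ± 71.9 (log2 change -4.65 ± 0.3, adjusted p = 1.2e-07), Igf1 from 115 ± 32.6 to 21.4 ± 3.48 and C1qb from 19400 ± 872 to 6570 ± 2620. Csf1r fell from 8150 ± 2050 to 3330 ± 581 and Gas6 from 4200 ± 161 to 1420 ± 465. Mcm7 fell from 242 ± 15.6 to 107 ± 26.8 and Tk1 from 204 ± 34 to 56 ± 33.1.

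By edgeR, 1040 genes differed, 573 higher and 467 lower in 4T1 CM, and 143 of the higher ones were partner-enriched. Leaving out co-culture in DMEM 1 gave 548 genes and co-culture in DMEM 2 gave 614. Of 30 cell-cycle genes 17 fell (21 adjusted over the list alone; adjusted p = 6.16e-13, 0.168 with an estimated correlation). Of 22 protease and inhibitor genes 11 rose and 2 fell, as many when adjusted over the list alone (adjusted p = 2e-06, 0.0769), and 6 of the risers are not partner-enriched. Lists of 21 fibroblast markers, with 2 higher (2 adjusted over the list alone; adjusted p = 0.0122, 0.591), and 25 collagen and matrix genes, with 4 higher (5 adjusted over the list alone; 0.0127, 0.621), were called higher too. All of these risers are partner-enriched, and the fibroblast share was 8.59% in 4T1 CM against 3.55% in DMEM. Of 20 hypoxia genes 10 rose, 3 of them not partner-enriched (14 adjusted over the list alone; adjusted p = 3.89e-08, 0.0647), and of 18 glycolysis genes 7, 5 of them not partner-enriched (10 adjusted over the list alone; adjusted p = 2.73e-06, 0.0958). Of 27 macrophage marker genes 10 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 6.11e-06, 0.194). The lists of MHC class II presentation (adjusted p = 0.297) and interferon response (0.255) were not called.

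The last comparison set macrophages in mono-culture in 4T1 CM beside those in co-culture in DMEM, 2 groups that differ in partner and medium together. Genes of MHC class II presentation, H2-Aa and Cd74, the interferon regulator gene Irf7 and Mmp8 were higher in mono-culture in 4T1 CM. Cell-division genes, Bub1b and Top2a, and Spp1 and Arg1 were lower. H2-Aa averaged 9450 ± 4070 (n = 4) against 72.9 ± 64.7 (n = 3), a log2 change of 7.08 ± 0.78 (adjusted p = 1.41e-05). Irf7 averaged 2630 ± 507 against 356 ± 38.3, Top2a 12.2 ± 2.51 against 235 ± 57.2 and Spp1 1960 ± 540 against 27700 ± 10200. Bub1b had no read in the 4 mono-cultures and 45.2 ± 6.13 in co-cultures, at least 59.3-fold lower against a floor of 3 reads over the group. By edgeR, 1462 genes differed, 629 higher and 833 lower, and 355 of the lower ones were partner-enriched. Alternative activation was not called as a list by camera (adjusted p = 0.134), with 7 of 13 genes lower and 1 higher. Proinflammatory macrophage genes were not called either (0.519), with 7 of 16 lower and 3 higher. All 8 MHC class II genes were higher (8 adjusted over the list alone; adjusted p = 2.54e-13, 0.0769 with an estimated correlation), and so were 22 of 33 interferon-response genes, with 1 lower (27 and 1 adjusted over the list alone; adjusted p = 5.97e-15, 0.108). All 30 cell-cycle genes were lower (30 adjusted over the list alone; adjusted p = 9.05e-32, 0.0647).

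**Figure D5:**
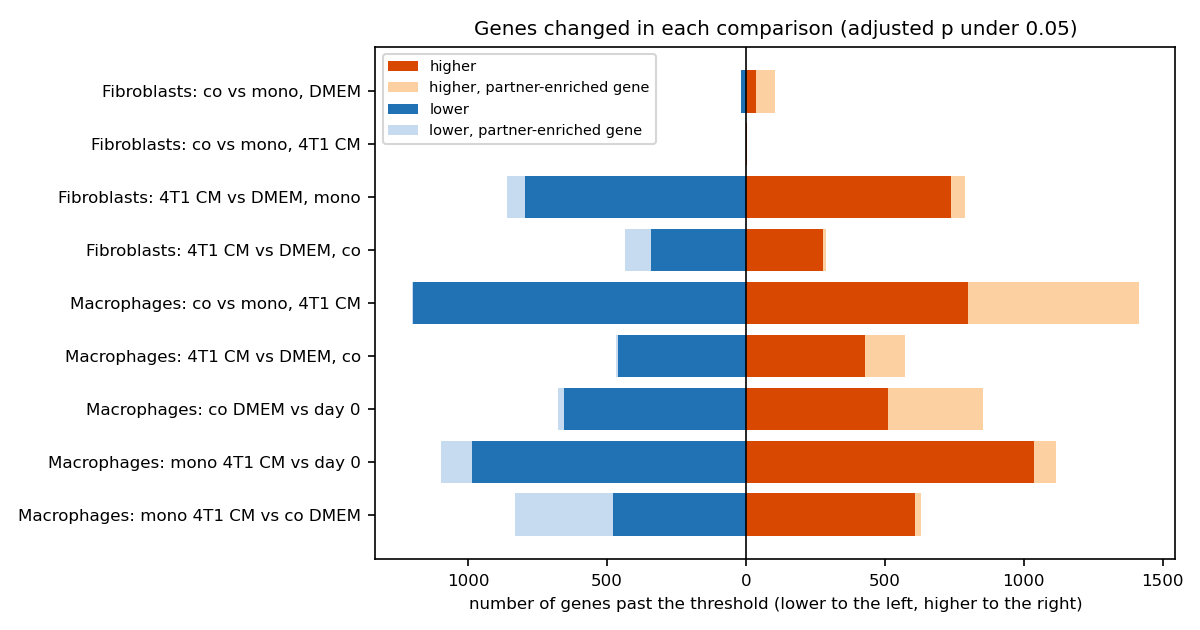
Number of genes with an adjusted p under 0.05 in each contrast, higher to the right and lower to the left, with partner-enriched genes in the pale shade. In fibroblasts co-cultured in DMEM, 68 of 106 higher genes are partner-enriched, and in macrophages co-cultured in 4T1 CM 617 of 1415.

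The genes of ligands and receptors that pass between both cell types were listed in advance. The fibroblast list of 37 was not called in any contrast, but camera tests for a shared direction and its members went both ways. For 4T1 CM in mono-culture 6 rose and 8 fell (13 and 12 adjusted over the list alone). In co-culture 9 rose and 7 fell (10 and 10). In macrophages the list of 31 was called higher in co-culture in DMEM than at day 0 (14 rose and 2 fell, 17 and 3 adjusted over the list alone; adjusted p = 0.000399, 0.0958 with an estimated correlation), with 6 of these 14 risers not partner-enriched. It was also called higher in co-culture than in mono-culture in 4T1 CM (14 rose and 6 fell, 15 and 7 adjusted over the list alone; adjusted p = 0.0375, 0.239). Of these 14 risers 3 are not partner-enriched, and with an estimated fibroblast part subtracted the list was not called (adjusted p = 0.641, and 0.828 without co-culture in 4T1 CM 3). Over all contrasts, camera with the preset correlation called 61 of 140 list tests in fibroblasts and 78 of 135 in macrophages. With an estimated correlation none was called in fibroblasts and 4 in macrophages.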

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

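The interaction contrast was planned; the splits of the samples and the tests of partner RNA, of glial and muscle cells and of the authors' scaling were chosen only after the results were seen.

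C1qb, Trem2, Fcrls and Csf1r rose in fibroblasts co-cultured in DMEM, and macrophage genes stood out because that change differed between media: the interaction was -6.3 for Trem2, -5.08 for Fcrls, -5.11 for Cybb, -4.23 for Slc15a3 and -3.81 for Csf1r on the log2 scale. Macrophage RNA or cells among the sorted fibroblasts could account for the rise in DMEM. The markers that define the share of 1.23% were left out. The 100 most abundant other macrophage-enriched genes with a mono-culture baseline under the predicted amount were taken. Of these, 93% rose by at least 0.5 of that amount. Their median implied share was 1.11% (quartiles 0.922% to 1.35%), and Spearman's rho between the rise and the level in macrophages was 0.85. Without the condition on the baseline, which was added after the value was seen, 66% did so and rho was 0.00647. Genes with a higher baseline thus leave the matter open. Over the 68 macrophage-enriched genes called higher, markers included, the median implied share was 1.19% (quartiles 0.994% to 1.48%). It was well above that for Psmb8 (15.4%), Hpse (13.1%), Arrb1 (9.36%) and Slc15a3 (2.97%). No biological explanation was tested, and a rise of these genes within the fibroblasts stays open. The difference between media was not covered by these tests. For Csf1r it also holds a rise in mono-cultures, to which no macrophages were added (17.9, 20.3 and 20.8 normalized reads in DMEM, 105 and 139 in 4T1 CM). Their macrophage share was 0.0244% in DMEM and 0.172% in 4T1 CM, and whether some macrophages were present was not tested.

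Glial and muscle genes drew attention through Mybph, whose co-culture change differed between media by 5.12: of 15 glial genes measured 10 fell in mono-culture in 4T1 CM and 11 in co-culture, and of 19 muscle genes 16 and 1. Fewer muscle cells may explain the co-culture part, but so may lower expression per cell, since a similar share kept by most members would follow from both. In co-culture 93.8% of 16 muscle members kept a share of their DMEM level within 2-fold of the median of 34.9% (93.8% to 100% with each library left out). The medians were 15%, 25.9%, 48% and 41.8% in co-cultures 1 to 4, with 68.8% of members within 2-fold in co-culture 1. In mono-culture, where the loss was close to complete, 23.5% of 17 muscle members (5.88% to 35.3%) and 25% of 12 glial members (16.7% to 33.3%) did so around their medians. For glial genes in co-culture it was 75% of 12 around 17.1%, which was 5.09% without co-culture 4 and 1.33%, 3.56%, 12.1% and 42.8% in co-cultures 1 to 4. In these 3 tests too, fewer cells and lower expression per cell cannot be told apart, because members or libraries differed too much and levels left in mono-culture were near 0. The authors' scaling is argued against by a median log2 change of -4.98 (quartiles -5.86 to -2.25) over all 34 members in mono-culture in reads with no factor applied, and repression of these genes by 4T1 CM in the cells that make them was not tested and stays open.

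Cell-cycle genes rose in macrophages co-cultured in 4T1 CM against mono-culture, a comparison in which the fibroblast share reached 20.8% in replicate 3. Fibroblast RNA as the whole cause is argued against, since that share accounts for a median of 30.9% of the rise over the 4 libraries, though for 139% in replicate 3. With the fibroblast part subtracted and that replicate left out, the list had an adjusted p of 2.72e-13 by camera with the preset correlation and 0.13 with an estimated one, with which it was not called before subtraction either (0.162). By limma on log2 values 27 of 30 genes rose with nothing subtracted (median log2 change 2.06, quartiles 1.4 to 2.9), 8 with the part subtracted (0.97, 0.51 to 1.88) and 18 with replicate 3 left out too (1.52, 0.87 to 2.7), so part of the rise may be fibroblast RNA. That fibroblasts may keep macrophages dividing in 4T1 CM is a hypothesis from the same data and was not tested.

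Other splits of the same libraries were counted where both groups had at least 3. For 4T1 CM in co-cultured fibroblasts (725 genes) 1 of 35 splits gave as many, the real one, and the highest other gave 307. For co-culture in 4T1 CM in macrophages (2618 genes, highest other 0) and 4T1 CM in co-cultured macrophages (1040, highest other 167) 1 of 35 splits gave as many. It was also 1 of 35 for day 0 against mono-culture in 4T1 CM (2214, highest other 672) and that group against co-culture in DMEM (1462, highest other 212). A share of 1 in 35 is under 0.05, which argues against chance for these 5 counts. It does not exclude chance, since 1 in 35 is the smallest share possible here and the macrophage counts share libraries. For co-culture in DMEM in fibroblasts (124 genes; highest other 0) and day 0 against co-culture in DMEM in macrophages (1531; 0), 10 splits are too few for a share under 0.05.

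The co-culture change differed between media, tested by the interaction, for 18 genes. Besides those above, the difference was 3.51 for Syngr1, 1.65 for Hmox1 and 1.35 for Tmem150a. Among lists called by the same test, the median difference was -4.68 for macrophage markers, -3.92 for complement and Fc receptors, -2.97 for alternative activation and -0.85 for proinflammatory macrophage genes. It was -1.22 for endothelial genes, -0.88 for cytokines, -0.76 for interferon response, -0.76 for MHC class I presentation, -0.7 for NF-kB and acute phase and -0.67 for cell cycle. It was -0.58 for hypoxia, -0.35 for glycolysis, -0.25 for collagens and 0.39 for oxidative stress, and no list was called with an estimated correlation.

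Single libraries lay far from the others of their group for 16 of 131 genes and groups tested. Chance gives about 1 in 20 for normally distributed values. A gene with reads in only 1 library of a group, as Cdh5, Cybb, Ciita and Dcn below, is flagged by construction. The count is therefore not comparable with that rate. Among fibroblast co-cultures in 4T1 CM, replicate 1 had 2.09 normalized reads of Cdh5, 2.09 of Cybb and 11.5 of Mybph. Among macrophage co-cultures in 4T1 CM, replicate 1 had 146 of H2-Aa and 97.4 of H2-Eb1, replicate 2 had 106 of Tk1, replicate 3 had 940 of Csf1 and 1080 of Mmp8, and replicate 4 had 180 of Mmp13 and 0.889 of Ciita. Among macrophage mono-cultures in 4T1 CM, replicate 1 had 1230 of Aif1, 1860 of Il1b and 2050 of Itgam, replicate 2 had 5.88 of Ube2c, replicate 3 had 6.04 of Dcn and replicate 4 had 1140 of Fcgr2b.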

How the results depend on the processing

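Leaving out fibroblast co-cultures in 4T1 CM 3 and 4 and subtracting a partner part were chosen after seeing the data. The other alternatives were planned. The partner part was subtracted from every library, mono-cultures too, and values under 0 were set to 0. This also lowers the mono-culture values that the changes rest on. Of 178 named gene values 144 kept their direction and their call in every alternative; of 3030 comparisons 134 lost the call, 6 gained it and 6 changed sign, and where nothing else is stated the cause was not tested. With the macrophage part subtracted, C1qb and Fcrls went to -0.15 and 0 for co-culture in DMEM and to 1.36 and 0.24 for 4T1 CM in co-culture, while for co-culture in DMEM Trem2, Adgre1, Csf1r and Apoe went from 5.23, 4.89, 3.08 and 2.46 to 1.58, 1.22, 1.03 and 0.94 and Lyz2 from 5.51 to 6.12, none of them passing (adjusted p = 0.624, 0.559, 0.148, 0.194 and 0.0517); with the fibroblast part subtracted, macrophage Csf1 went to -0.1 in co-culture in 4T1 CM, and without MAC_co_CM replicate 1 Itgam, not called, went to -0.05 (-0.05 to 0.19 over all libraries left out). For co-culture in DMEM in fibroblasts (124 genes) the count was 73 with a minimum of 20, 210 with DESeq2, 30 without partner-enriched genes, 205 with only the compared groups and 35 with the macrophage part subtracted (fewer genes or a lower value by construction). For co-culture in 4T1 CM (3) it was 0 with pseudocount 5, quantile normalization, the replicate block, edgeR or only the compared groups (1155 at an unadjusted p under 0.05 in limma), 5 with pseudocount 0.5, 1 with a minimum of 20 and 25 with DESeq2. For 4T1 CM in co-culture (725) it was 444 with only the compared groups and 1108 without co-cultures 3 and 4. For the interaction (18) it was 1 with the replicate block, 10 with edgeR, 137 with DESeq2, 5 without partner-enriched genes and 64 without co-cultures 3 and 4. A minimum log2 change of 1 left 1314, 580, 974, 1156 and 913 genes for macrophage co-culture in 4T1 CM, 4T1 CM in co-culture, co-culture in DMEM and mono-culture in 4T1 CM against day 0, and these against each other. With the fibroblast part subtracted, co-culture in DMEM against day 0 gave 925 and the last comparison 970. With each library left out, fibroblast counts ranged from 18 to 81 for co-culture in DMEM, 0 to 296 for co-culture in 4T1 CM, 535 to 1425 and 264 to 818 for 4T1 CM in mono-culture and co-culture, and 2 to 197 for the interaction; macrophage counts ranged from 548 to 1032 for 4T1 CM in co-culture and 984 to 1261 for co-culture in DMEM against day 0. Of 61 lists called in fibroblasts 0 were called with an estimated correlation and 24 with fry, which called 28 in all; of 78 in macrophages 4 and 69 were, and fry called 80 in all. Residuals did not show a pairing by replicate number, but they do not exclude one. Between libraries with the same number their median correlation was -0.05 in fibroblasts (-0.33 to 0.29) and -0.07 in macrophages (-0.37 to 0.45). At this depth the interaction test recovered 10 of 100 simulated 2-fold changes.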

Other observations

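The overlap of the response to 4T1 CM between cell types and the values of Csf1r and Pdgfrb were looked at only after the results were seen.

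Fibroblasts and macrophages sorted from co-cultures share part of their response to 4T1 CM. Mmp13, a collagenase gene, Ptgs1, which makes prostaglandin precursors, Plaur, the urokinase receptor gene, the transcription factor gene Cebpb, Hmox1 and Hmga2 were higher in both. Plxnd1, a semaphorin receptor gene, and Igfbp4, which binds insulin-like growth factors, were lower in both. Cd40, a receptor of the TNF family, was higher in fibroblasts and lower in macrophages, and L1cam and St3gal5 went the other way.

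The log2 change was 3.75 ± 0.77 in fibroblasts and 9.44 ± 1.17 in macrophages for Mmp13, 1.93 ± 0.23 and 3.11 ± 0.3 for Ptgs1, and 1.17 ± 0.18 and 2.13 ± 0.21 for Plaur. It was 1.35 ± 0.17 and 1.01 ± 0.2 for Cebpb, -1.38 ± 0.3 and -1.62 ± 0.28 for Plxnd1, and 2.24 ± 0.37 and -1.2 ± 0.36 for Cd40. Among 8080 genes tested in both and partner-enriched in neither, 179 were called in fibroblasts and 596 in macrophages. Of the 41 called in both, 22 were higher in both against 4.11 by chance, 8 lower in both against 2.57 and 11 opposite against 6.53. Across these genes, which are not independent replicates, Pearson's r was 0.155 and Spearman's rho 0.12. The fibroblast share of the macrophages was 8.59% in 4T1 CM against 3.55% in DMEM, and what it adds to the overlap was not tested.

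Csf1r and C1qb, genes of macrophages, were not in proportion in fibroblasts. Mono-cultures in 4T1 CM had 105 and 139 normalized reads of Csf1r and 1.97 and 4.95 of C1qb. Co-cultures in DMEM had 131, 154 and 258 of Csf1r and 175, 220 and 490 of C1qb. Mono-cultures in DMEM had 17.9, 20.3 and 20.8 of Csf1r. Lyz2, another macrophage gene, had 332 and 263 in mono-cultures in 4T1 CM and 50.1, 58.9 and 37.7 in mono-cultures in DMEM. It had 1450, 2310 and 3320 in co-cultures in DMEM. Csf1r lies 15536 bp downstream of Pdgfrb, a fibroblast gene on the same strand, which had 1100 and 1320 in mono-cultures in 4T1 CM and 2030, 1690 and 1320 in mono-cultures in DMEM.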
